A study of Homo sapiens with 12 samples.

How the data were processed

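The study measured RNA of HepG2 cells infected with a retrovirus carrying KLF6 or with the empty vector pBabe, at 48 h and 72 h, on 12 arrays, 3 per group. Per the labels, the cells were grown in DMEM with serum, total RNA was extracted with a column kit and converted to biotin-labelled cRNA by in vitro transcription, and the label was read as Cy5. The scanner and the version of its software are not given in the sources used here. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples.

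Per the file headers, each array's file holds, for every spot, the mean intensity of the spot, the median intensity of its local background, the background-subtracted intensity, a normalized intensity and a quality code. From the values, the subtracted intensity equals the spot mean minus the background median, and the normalized intensity divides it by 1 factor per array, so that the array's median is near 1. The deposited series table holds the same normalized intensity on a linear scale: all 55584 of its value rows matched a scanner spot in all 12 arrays, within a tolerance of 1e-06. How the authors processed the values further is not given in the sources used here.

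Of the 55584 spots, 744 were controls (384 negative and 360 positive) and 54840 were probes. A probe took a gene symbol where its RefSeq mRNA accession appears in a reference list of accessions and symbols. Of 15641 probes with such an accession, 14513 matched 1 symbol and 0 matched several, and 40327 probes had no symbol. The symbol match gave 0 probes for KLF6, so the planned results on the KLF6 level were not analysed here.

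The intensities were corrected for background with limma 3.58.1 (normexp, offset 50) in R 4.3.3, with data.table (version 1.17.8). Values of masked or irregular spots were set to missing, controls were removed, and the log2 values were quantile normalized between arrays. A probe was tested if the software called it good on at least 3 of the 12 arrays, which left 17252 probes, of which 6999 carried a symbol, for 6689 genes. A linear model with a mean for each of the 4 groups was fitted with limma (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons were KLF6 against the vector at 48 h, at 72 h and on average, the difference of these effects between the times, and 72 h against 48 h in each arm. The fit of all 12 arrays left 8 residual degrees of freedom, and the fit without the 2 conflicting arrays left 6. An exact permutation test of 3 arrays against 3 could not give a p under 0.1, so limma, which pools the spread across probes, was used. The number of arrays limits the precision. Folds are given with 95% intervals from the moderated model. Where every value of a group was near background, the fold is a lower bound set against the level of the background.

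A set of 42 gene lists was written down, with the comparisons, the alternatives and the naming rule, before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with 1 probe per gene, the one with the highest mean; 38 lists had at least 5 measured members. An estimated correlation and fry were the alternatives. Genes were named by rule. At 48 h, at 72 h and on average these were the up to 10 genes with the largest rise and the up to 10 with the largest fall among those past the threshold whose groups did not overlap. Where fewer than 5 passed in a direction, the 10 with the smallest p were named as values. For the time comparisons the 5 largest of each direction were named, and of each list described, up to 4 members with the smallest p.

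Other settings fixed at that time were the software's background subtraction, its normalized intensity, the series table, median scaling, cyclic loess, no filter and a stricter filter on quality, array weights, no intensity trend, a robust prior, a date block, a replicate block, 1 probe per gene, each comparison's own arrays, each array left out in turn, and both arrays left out whose file name and label conflict. Added after seeing the data were the removal of the 3 arrays with under 10000 probes called good, normalization without the conflicting arrays, contaminated spots set to missing, and all settings run on the 10 arrays left without the conflicting pair. The replicate numbers did not pair the arrays: after removal of group means, the correlation of residuals between arrays of the same number and time ran from -0.030 to 0.045.

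The pipeline was tested on simulated data built from the residuals of each fit, with 100 of 16001 probes changed at each of 2 sizes. With all 12 arrays it recovered 0 of 100 probes changed 2-fold and 2 of 100 changed 4-fold at 48 h, 0 and 16 at 72 h, and 2 and 71 on average. With the 10 arrays it recovered 32 and 83 at 48 h, 11 and 66 at 72 h, and 57 and 92 on average, and at most 3 unchanged probes were called. Camera recovered the 1 raised list of 20 in each fit and called 0 of the others. The residuals were shuffled separately within each array, so the simulated probes were not correlated, and the list was raised by 1 log2 unit. The simulation therefore cannot show how the preset correlation performs with correlated members or smaller shifts. The median residual SD was 0.69 log2 units with all 12 arrays and 0.32 with the 10 arrays. Figures were drawn with matplotlib 3.10.9, and tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.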

Results

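HepG2, a human line from a liver tumour, was infected with a retrovirus carrying KLF6, a zinc-finger transcription factor, or with the empty vector pBabe. RNA was taken at 48 h and at 72 h, and each RNA was hybridized to a 1-colour oligonucleotide array. The labels give 4 groups of 3 arrays, 12 arrays in all. They do not say whether the replicates were separate infections. Each array held 54840 non-control probes, of which 14513 were matched to 1 gene symbol each, for 13454 genes. The match gave 0 probes for KLF6, so the level of KLF6 was not analysed here.

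The number of probes that the scanner software called good stands here for the depth of an array. It was 8521 on pBabe 48 h replicate 2, 7755 on the library labelled KLF6 72 h replicate 1 and 1347 on the library labelled pBabe 72 h replicate 1, and between 11374 and 16368 on every other array. The library labelled pBabe 72 h replicate 1 had 96.8% of its probes near background, and its rank correlation across probes with any other array was at most 0.197, against up to 0.768 between other arrays. The file names of the libraries labelled KLF6 72 h replicate 1 and pBabe 72 h replicate 1 point to the other vector than their labels. The labels were kept. Each comparison is given with all 12 arrays and, as planned, without these 2 arrays, written below as the 10 arrays.

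**Figure D1:**
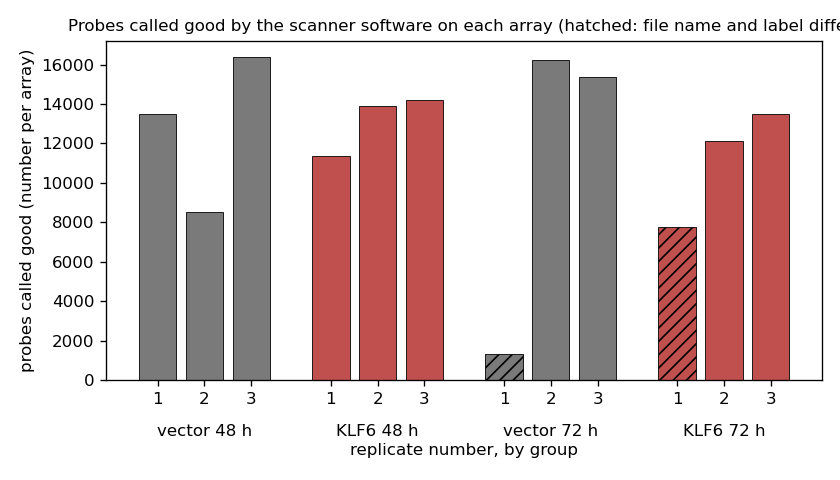
Number of probes that the scanner software called good on each array, by group and replicate. Grey bars are empty vector arrays, red bars KLF6 arrays, and hatched bars the 2 arrays whose file name and label differ; the lowest bar stands at 1347 probes and the highest at 16368.

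The comparison at 48 h asks what KLF6 changed early after infection. In the 10 arrays, which hold all 3 arrays of each 48 h group, TSPO, a protein of the outer mitochondrial membrane that binds cholesterol, rose 3.30-fold (95% interval 2.44 to 4.47) with KLF6. Its mean log2 intensity was 12.09 ± 0.04 with KLF6 and 10.36 ± 0.32 with the vector (SD, n = 3 each; limma adjusted p = 0.0172). SPINK1, a secreted trypsin inhibitor, fell 3.69-fold (2.53 to 5.38), from 14.09 ± 0.12 to 12.20 ± 0.32 (limma adjusted p = 0.0206). BEX1, a small adaptor protein known from neurons, fell 2.73-fold (2.07 to 3.60), from 12.54 ± 0.18 to 11.09 ± 0.19 (limma adjusted p = 0.0178). The arrays of both groups did not overlap for these 3 genes, which 10% of genes show by chance with 3 arrays against 3. The naming rule required this, so it adds no support.

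With limma, 9 of 17251 probes passed at 48 h in the 10 arrays, 4 higher and 5 lower, and 6 of them had no gene symbol. The genes with the next smallest p did not pass: LARP6 was 2.78-fold lower, MT1H 2.62-fold lower, JAM3 2.52-fold lower, NME5 2.07-fold lower, GSTA1 2.99-fold lower, NDUFS6 2.25-fold lower and SF3B6 1.77-fold lower, with limma adjusted p from 0.0890 to 0.150. Genes of S phase and DNA replication shifted down as a list: of 20 measured members 17 were lower and 3 higher, the median log2 change was -0.39, and camera's adjusted p was 0.00326 (adjusted p = 0.198 with an estimated correlation). MCM5, a subunit of the replicative helicase, was at -0.97 ± 0.28 (standard error), CHAF1A, a histone chaperone, at -0.45 ± 0.17, and MCM10, a replication initiation factor, at -0.41 ± 0.16. E2F1, the transcription factor that drives many of these genes, was at least 1.40-fold higher, set against only 2 measured vector arrays, neither well above background. It was the 1 member to pass adjusted over the list alone, which those 2 arrays are too few and too dim to carry, and 0 passed over all probes. Of the 6 measured genes of the metallothionein list, which bind zinc and copper or respond to them, 5 were lower and 1 higher, with a median of -0.86 and a camera adjusted p of 0.00649 (adjusted p = 0.198 with an estimated correlation). MT1H was at -1.39 ± 0.23 and MT1F at -0.95 ± 0.25; these 2 passed adjusted over the list alone and 0 passed over all probes. Metallothionein genes are close in sequence, so their probes are not independent measures.

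The ribosome biogenesis list (14 of 21 lower, median -0.24) and the proteasome list (16 of 25 lower, median -0.16) each had a camera adjusted p of 0.0291 at 48 h (adjusted p = 0.650 with an estimated correlation for each). UTP4, a ribosomal RNA processing factor, was at -0.91 ± 0.17 and was the 1 member of its list to pass adjusted over the list alone; 0 proteasome members did. Each call held in 10 of 17 settings. Both ended under cyclic loess (adjusted p = 0.131 and 0.390), the software's own normalized intensity (0.0835 and 0.613) and median scaling (0.141 and 0.723). They also ended without KLF6 48 h replicate 1 (0.106 each), pBabe 48 h replicate 2 (0.124 each) or pBabe 48 h replicate 3 (0.135 and 0.233). Ribosome biogenesis ended with spots of contaminated background set to missing (0.292) and the proteasome with a date block (0.102). With the preset correlation, the metallothionein call at 48 h held in 16 of 16 settings of scaling, block or arrays. The S phase call held in 17 of 17, and the camera adjusted p were at most 0.0253 and 0.0338 in that order. With spots of contaminated background set to missing, too few metallothionein genes had complete values, so that list was not tested there.

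Limma passed 0 of 17251 probes at 48 h with all 12 arrays, and 167 had an unadjusted p under 0.05, where 863 would be so by chance. The 10 genes with the smallest p there did not pass (adjusted p = 1.00). SEL1L3 was 3.17-fold higher, PRKG2 2.43-fold higher and SCN9A 2.42-fold higher, E2F1 at least 1.40-fold and SLC6A11 at least 1.24-fold higher. MTHFS was at least 1.84-fold lower, SULF2 at least 1.61-fold, EXOSC9 at least 1.37-fold, PPP4R3B at least 1.30-fold and PEX11A at least 1.30-fold. Camera called the metallothionein list alone among 38 tested lists with all 12 arrays (median -0.86, adjusted p = 0.0290, and adjusted p = 0.994 with an estimated correlation). In the 10 arrays the count of 9 became 0 with the software's normalized intensity, with median scaling, with a replicate block or without the intensity trend, and 3 with 1 probe per gene. It became 0 without KLF6 48 h replicate 1, 2 or 3, 5 without pBabe 48 h replicate 1, and 4 without pBabe 72 h replicate 2 or 3. TSPO, SPINK1 and BEX1 kept their direction in all 21 settings run, and passed in 14, 10 and 12 of them. Leaving out 1 array could not reverse them, since their groups did not overlap. The settings of trend, prior and 1 probe per gene, and a 72 h array left out, do not change a 48 h fold at all.

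The comparison at 72 h asks the same a day later, with 2 arrays per group once the conflicting libraries are left out. TSPO was 3.70-fold higher with KLF6 (2.56 to 5.36; log2 intensity 11.95 ± 0.30 against 10.06 ± 0.09, SD, n = 2 each), SPINK1 4.51-fold lower (2.84 to 7.15) and BEX1 2.74-fold lower (1.95 to 3.84). None of these passed; the limma adjusted p were 0.0605, 0.0647 and 0.104. Among the other genes with the smallest p, XPNPEP2 was 2.11-fold higher and ITIH3 2.06-fold higher. JAM3 was 2.71-fold lower, MARS1 2.58-fold lower and ATP5F1C 2.11-fold lower. With all 12 arrays and the labels kept, SPINK1 and MARS1 went the other way at 72 h, higher with KLF6, and did not pass. APOM was 2.41-fold lower and ERCC6L2 at least 1.97-fold lower, each from 1 measured KLF6 array, assumed to vary like the other groups.

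At 72 h in the 10 arrays limma passed 0 of 17243 probes, with 901 at an unadjusted p under 0.05 and 862 by chance, and camera called 0 lists. The count became 5 without pBabe 48 h replicate 2, which left both 72 h groups as they were. It also rose without KLF6 72 h replicate 2 or 3 or pBabe 72 h replicate 2. In those fits 1 array was left in a 72 h group, so no count is given. Among the other settings, the count was 11 with spots of contaminated background set to missing, 8 with array weights and 3 with 1 probe per gene. It was 2 with cyclic loess, 2 with a date block and 1 with the software's background subtraction. Limma passed 0 of 17252 probes with all 12 arrays, with 824 at an unadjusted p under 0.05. The 10 genes with the smallest p had an adjusted p of 0.604. SCD, a fatty acid desaturase, was 4.44-fold lower, SLC48A1 4.29-fold lower, CPSF2 3.81-fold lower and BCLAF1 2.89-fold lower. For SLC48A1, CPSF2 and BCLAF1 only 1 of 3 KLF6 arrays was above background, so these folds rest on values near background. GJB1, a gap junction protein, was 2.41-fold higher, and SON, RCAN1, RNF6 and ORC2 were at least 1.68-fold, 1.59-fold, 1.56-fold and 1.05-fold lower. SART3, at a mean log2 intensity of 7.55 ± 0.19 with KLF6 and 8.75 ± 0.44 with the vector (SD, n = 3 each), was too near background for a bound.

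The average of both times asks which genes KLF6 changed over both times together. In the 10 arrays 35 of 17242 probes passed with limma, 15 higher and 20 lower with KLF6, and 21 of them carried a gene symbol. SPINK1 fell 4.08-fold (3.03 to 5.49; log2 intensity 14.05 ± 0.13 with the vector and 12.05 ± 0.47 with KLF6, SD, n = 5 each; limma adjusted p = 0.00201). TSPO rose 3.50-fold (2.76 to 4.44; 10.24 ± 0.29 and 12.03 ± 0.17, n = 5 each; limma adjusted p = 0.00123), and BEX1 fell 2.73-fold (2.20 to 3.40; limma adjusted p = 0.00201). Also higher were XPNPEP2, a membrane aminopeptidase that cleaves bradykinin (1.98-fold), KDELR3, a receptor that returns proteins to the endoplasmic reticulum (1.95-fold), ITIH3, a secreted hyaluronan-binding plasma protein (1.95-fold), and PXDC1 (1.68-fold). Their adjusted p ran from 0.0210 to 0.0447.

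On average in the 10 arrays, GSTA1, a glutathione transferase abundant in liver, fell 2.55-fold (1.83 to 3.56), TXNRD1, the cytosolic thioredoxin reductase, 2.04-fold (1.61 to 2.60), and MT1H, a metallothionein, 2.26-fold (1.72 to 2.97), with adjusted p of 0.0392, 0.0352 and 0.0352. HAMP, the precursor of the iron hormone hepcidin, fell 2.34-fold (1.75 to 3.12; adjusted p = 0.0360). JAM3, a junctional adhesion molecule, fell 2.61-fold, LARP6, a collagen mRNA binding protein, 2.46-fold, ZIC2, a zinc-finger transcription factor, 2.04-fold, and SS18L2 1.83-fold, with adjusted p from 0.0150 to 0.0447. For all 15 of these genes the KLF6 and vector arrays did not overlap within either time, which the naming rule required. A further 6 genes passed outside the naming rule and are named after their values were seen: IGFBP1, a secreted binding protein of insulin-like growth factors, rose by a log2 change of 1.14, and FDFT1, ATP5F1C, ASPH and SF3B6 fell by 0.94, 0.84, 0.79 and 0.72. The sixth, ERCC6L2, passed on 1 measured KLF6 array at 72 h that was not well above background, so no size is given for it.

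The metallothionein list was lower in 6 of 6 members on average (median -0.57, camera adjusted p = 0.00695, adjusted p = 0.187 with an estimated correlation); 1 member passed over all probes and 2 adjusted over the list alone, MT1H and MT1F. The S phase list was lower in 17 of 20 members (median -0.22, camera adjusted p = 0.00695, adjusted p = 0.187 with an estimated correlation). MCM5 at -0.82 ± 0.22 and POLA1, a subunit of the priming DNA polymerase, at -0.62 ± 0.17 were its 2 members that passed adjusted over the list alone, and 0 passed over all probes. Ribosome biogenesis was lower in 14 of 20 members (median -0.24, camera adjusted p = 0.0344, adjusted p = 0.402 with an estimated correlation), with 4 members past the threshold adjusted over the list alone and 0 over all probes. MYC, the transcription factor that drives this programme, was at -0.94 ± 0.19, NOP58 at -0.81 ± 0.15, UTP4 at -0.75 ± 0.14 and POLR1B, a subunit of RNA polymerase I, at 0.41 ± 0.12. Without KLF6 72 h replicate 3 the metallothionein and S phase calls both ended at an adjusted p of 0.0921, and the ribosome biogenesis call held in 10 of 17 settings.

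Lists tied to KLF6 or growth arrest by earlier work did not pass. Of 15 measured genes described elsewhere as regulated by KLF6, 11 were higher and 4 lower (median 0.12, camera adjusted p = 0.685, 10 arrays). That list was not sorted by the direction described, and camera tests a shift in 1 direction, so members moving both ways would cancel. PLAU, the urokinase gene, was at -0.78 ± 0.20 and was the 1 member to pass adjusted over the list alone. The 18 measured genes of the p53 pathway and CDK inhibitors split evenly, 9 higher and 9 lower (median 0.01, mean -0.04, camera direction down, adjusted p = 0.932), with 0 past the threshold in either count. All 6 measured KLF and SP factors were higher (median 0.27), with a camera adjusted p of 0.197.

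**Figure D2:**
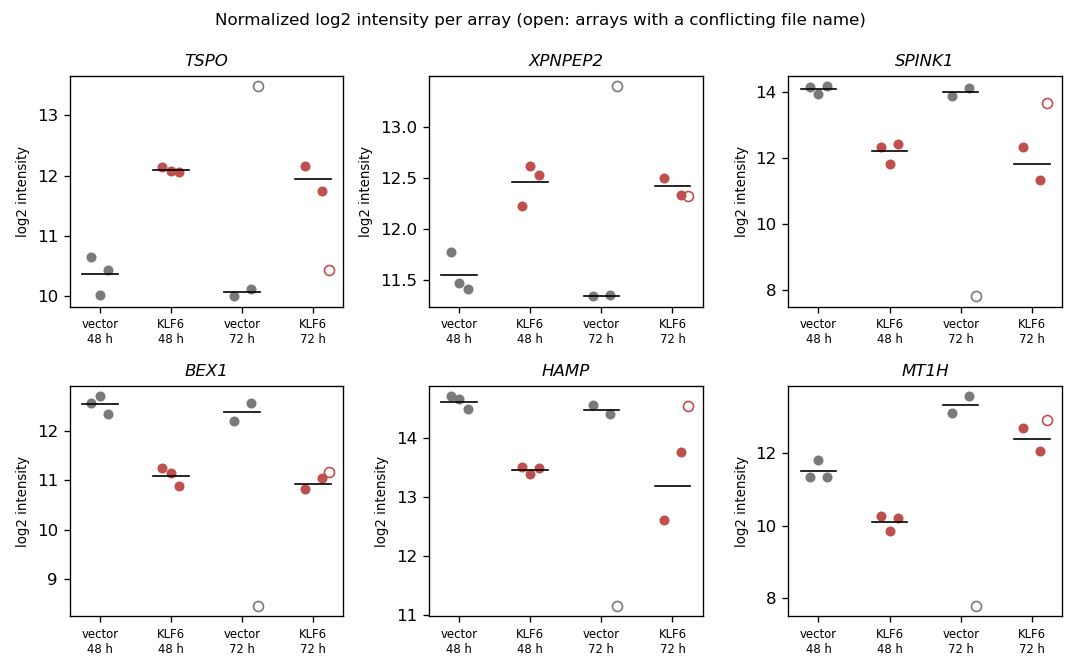
Normalized log2 intensity of 6 genes on each array, by group. Filled points are the 10 arrays, open points the 2 arrays with a conflicting file name, and lines the group means of the filled points; TSPO and XPNPEP2 are higher and SPINK1, BEX1, HAMP and MT1H lower with KLF6 at each time in the filled points.

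For the average, limma passed 0 probes with all 12 arrays, with 542 at an unadjusted p under 0.05, and camera called 0 lists. The 10 genes with the smallest p had an adjusted p of 0.863. EMP3 was 2.58-fold, LIMD2 2.30-fold, PRKG2 2.12-fold and CYP2J2 1.93-fold higher. BCLAF1 was 2.12-fold lower, with 2 of 6 KLF6 arrays above background, MAT2B 1.94-fold, SULF2 at least 1.37-fold and EXOSC9 at least 1.18-fold lower. PCGF6 was too near background for a bound, and SON, lower as well, was not well above background on any KLF6 array at 72 h. In the library labelled KLF6 72 h replicate 1, the log2 intensity was 10.43 for TSPO and 13.66 for SPINK1, against means of 11.95 and 11.83 in the other KLF6 72 h arrays; the vector arrays kept at 72 h had a mean of 10.06 for TSPO. It was 11.17 for BEX1 and 12.32 for XPNPEP2, near the means of 10.94 and 12.42 in the other KLF6 72 h arrays.

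The count of 35 in the 10 arrays became 0 with the software's normalized intensity, 2 with median scaling, 7 without the intensity trend and 8 with the replicate block, and rose to 69 with cyclic loess and to 160 with array weights. Without KLF6 48 h replicate 1, 2 or 3 it was 9, 9 and 8, and without pBabe 48 h replicate 2 or 3 it was 122 and 14. Without a further 72 h array, 1 array was left in a group, so no count is given. The count rose without either KLF6 72 h array, with most calls lower, and fell without either pBabe 72 h array. The 15 named genes kept their direction in all 21 settings, though leaving out 1 array could not reverse groups that did not overlap. The settings of trend, prior and 1 probe per gene do not change a fold at all. SPINK1 passed in 20, TSPO and BEX1 in 19 each, and ZIC2 and PXDC1 in 7 each. The software's normalized intensity and median scaling moved the median of all probes to -0.15 and -0.16 on average, and to 0.40 and 0.39 from 48 h to 72 h in vector cells. Relative to that median, the metallothionein list stood at -0.53 and -0.54 on average, the S phase list at -0.30 in both and the ribosome biogenesis list at -0.23 in both.

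Whether the KLF6 effect differed between 48 h and 72 h was tested as an interaction. In the 10 arrays limma passed 0 of 17242 probes, with 353 at an unadjusted p under 0.05, and camera called 0 lists. With all 12 arrays limma passed 0 as well, with 194 at an unadjusted p under 0.05. The metallothionein and S phase lists, called at 48 h and not at 72 h, are therefore not shown to differ between the times. The count in the 10 arrays was 72 without KLF6 72 h replicate 3, 1 without pBabe 72 h replicate 2, and 3 with spots of contaminated background set to missing.

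The comparison of 72 h with 48 h asks what changed with time in culture in each arm. MT1H rose in both arms of the 10 arrays, 3.58-fold (2.43 to 5.28) with the vector and 4.83-fold (3.28 to 7.12) with KLF6, with limma adjusted p of 0.0111 and 0.00497. NALF2, an auxiliary subunit of a sodium leak channel, rose 3.52-fold and 3.74-fold. With the vector, P2RX3, an ATP-gated channel of sensory neurons, rose 4.84-fold, FOXR2, a forkhead factor, 3.23-fold, and LOXL2, a lysyl oxidase that crosslinks collagen, 3.17-fold. With KLF6, CTNND2, a catenin of neuronal junctions, rose 4.86-fold, SIM2, a transcription factor, 3.85-fold, and TGM4, a transglutaminase of prostate, 3.32-fold. APOM, a lipoprotein that carries sphingosine 1-phosphate, fell 2.90-fold (limma adjusted p = 0.0175) and ERCC6L2 at least 2.31-fold (limma adjusted p = 0.00579) with KLF6. Each rests on 1 measured array at 72 h, assumed to vary like the other groups. The library labelled KLF6 72 h replicate 1, left out here, had 14.66 for APOM, near the 48 h mean of 14.71.

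Limma passed 47 of 17244 probes with the vector, all higher at 72 h, and 47 of 17250 with KLF6, 44 higher and 3 lower. Of these, 29 passed in both arms, all higher in both, where 0.128 would be shared if the arms were independent. The arms were not fully independent, since 1 model gave each probe 1 estimate of spread for all groups. The metallothionein list rose in both arms: 6 of 6 members higher with the vector (median 0.82, camera adjusted p = 0.000534, adjusted p = 0.164 with an estimated correlation) and 5 of 6 with KLF6 (median 1.40, camera adjusted p = 4.14e-05, adjusted p = 0.0932 with an estimated correlation). In each arm 1 member passed over all probes; adjusted over the list alone 2 passed with the vector and 3 with KLF6, MT1G among them at 0.96 ± 0.34 and 1.41 ± 0.34. Glycolysis and gluconeogenesis genes shifted up as a list with the vector (12 of 15 higher, median 0.33, camera adjusted p = 0.00600, adjusted p = 0.644 with an estimated correlation) and with KLF6 (11 of 15, median 0.35, adjusted p = 0.0321, and adjusted p = 0.938 with an estimated correlation). PKM, a pyruvate kinase, was at 0.77 ± 0.19 with the vector and the 1 member past the threshold adjusted over the list alone; PCK1, an enzyme of glucose synthesis, was at 0.96 ± 0.36 with KLF6, where 0 passed. Hypoxia responsive genes shifted up with KLF6 (10 of 12 higher, median 0.38, camera adjusted p = 0.0340, adjusted p = 0.938 with an estimated correlation), with ERO1A, an oxidase of the endoplasmic reticulum, at 0.41 ± 0.21 and 0 members past the threshold adjusted over the list alone.

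**Figure D3:**
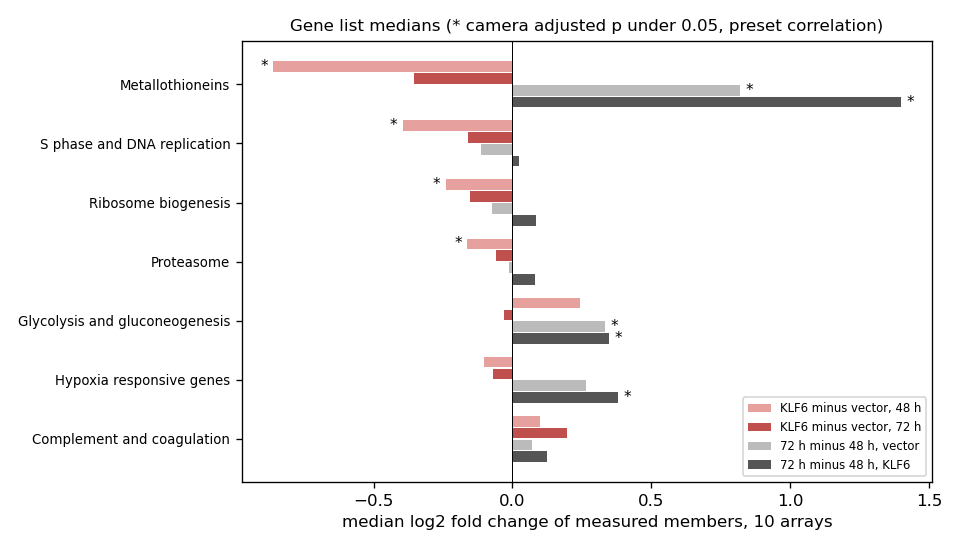
Median log2 fold change of the measured members of 7 gene lists in the 10 arrays, for KLF6 against the vector at each time and for 72 h against 48 h in each arm. Stars mark camera adjusted p under the threshold with the preset correlation; the metallothionein medians run from -0.86 at 48 h to 1.40 with time in KLF6 cells.

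All vector arrays at 48 h carry the earlier of 2 dates in their file names and all vector arrays at 72 h the later, so within-date values exist only in KLF6 cells; with a date block the 10 arrays gave 7 probes with the vector and 39 with KLF6. With all 12 arrays limma passed 0 probes in either arm, with 740 and 399 at an unadjusted p under 0.05, and camera called the metallothionein list with KLF6 (median 1.42, adjusted p = 0.000996, and adjusted p = 0.400 with an estimated correlation). In the 10 arrays both counts became 0 with the software's normalized intensity and with median scaling. They were 13 and 20 without the intensity trend, 13 and 18 with 1 probe per gene, and 139 and 78 with array weights. Both were 0 with the replicate block too. Its blocks lie within a time, so that fit compared 1 block-adjusted replicate of each time. It cannot test the mean change with time. With the vector the count was 29 and 31 without KLF6 48 h replicate 2 or 3, and 72 without pBabe 48 h replicate 2. Without pBabe 72 h replicate 2 or 3, 1 vector array was left at 72 h, so no count is given. The count fell in both cases, and without replicate 3 the calls were no longer all higher. With KLF6 the count was 14, 11 and 18 without KLF6 48 h replicate 1, 2 or 3, 156 without pBabe 48 h replicate 2, and 28 without pBabe 72 h replicate 2 or 3. Without KLF6 72 h replicate 2 or 3, 1 KLF6 array was left at 72 h, so no count is given. The count fell without replicate 2 and rose without replicate 3, where most calls were lower at 72 h, unlike in the main fit. The KLF6 glycolysis and hypoxia calls each held in 12 of 17 settings. Both ended with a date block (camera adjusted p = 0.0791 for glycolysis and 0.0919 for hypoxia). With the replicate block, which cannot test a change with time, camera gave 0.137 and 0.246. They also ended with spots of contaminated background set to missing (0.328 and 0.410). Without KLF6 48 h replicate 3 both ended too, at 0.157 for glycolysis and above 0.05 for hypoxia. Both ended as well without KLF6 72 h replicate 3, which left 1 KLF6 array at 72 h, so no p is given. The vector glycolysis call held in 14 of 17, and ended with a date block (0.687), with contaminated spots missing (0.0608) and without pBabe 48 h replicate 1 (0.0762).

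Markers of other cell types were mostly absent from the tested probes. Of the genes with a probe, 7 of 14 cholangiocyte and progenitor markers, 3 of 15 stellate cell and fibroblast markers, 2 of 15 endothelial markers, 1 of 19 leukocyte and Kupffer cell markers and 1 of 15 neuronal and embryonic kidney markers were called good on at least 3 arrays. The cholangiocyte list, the 1 with enough members for a test, had 3 members higher and 4 lower on average with KLF6 (median -0.19, camera adjusted p = 0.705, 10 arrays).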

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

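The counts of probes rest on which arrays are used and how they are scaled; the cause was not tested unless a value is given. The removal of 3 dim arrays, normalization after the removal, contaminated spots set to missing and the settings run on the 10 arrays were chosen after seeing the data. The settings meant for the KLF6 level were not run, since that level was not analysed here. With all 12 arrays, limma passed 0 probes in each of the 6 comparisons, and also with the replicate block and with the date block. The replicate numbers do not pair the arrays, and the replicate block cannot test a change with time. Without the 2 conflicting arrays the median residual SD dropped from 0.69 to 0.32. Signal over background limits the library labelled pBabe 72 h replicate 1 most: the 99th percentile of its signal was 5.42 times the level of the negative controls, against 180 times on pBabe 48 h replicate 3.

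At 48 h the count was 9 with array weights, 9 without both conflicting arrays, 9 with these left out before normalization, 8 without the 3 dim arrays and 7 with the comparison's own arrays, and 0 to 0 with each array left out in turn. At 72 h it was 10 with array weights, 5 without the 3 dim arrays, 8 with contaminated spots missing, and 0 to 10 with each array left out, highest without pBabe 72 h replicate 2 and 6 without replicate 3. On average it was 242 with array weights, 35 without both conflicting arrays, 36 with these left out before normalization, 122 without the 3 dim arrays, 5 with contaminated spots missing, and 0 to 7 with each array left out (7 without pBabe 72 h replicate 1 or 2, 4 without replicate 3). The difference between the times gave 4 with contaminated spots missing and 0 to 8 with each array left out (8 without pBabe 72 h replicate 2, 5 without replicate 3). From 48 h to 72 h in vector cells it was 3 with cyclic loess, 2 with probes good on all 12 arrays and 195 with array weights. It was 47 without both conflicting arrays, 45 with these left out before normalization and 72 without the 3 dim arrays. With contaminated spots missing it was 17, 2 higher and 15 lower. With each array left out it was 0 to 22: 22, all higher, without pBabe 72 h replicate 1, 9 without replicate 2, 1 higher and 8 lower, and 5, all lower, without replicate 3. In KLF6 cells it was 30 with cyclic loess, 2 with probes good on all 12 arrays, 146 with array weights, 47 without both conflicting arrays, 46 with these left out before normalization, 156 without the 3 dim arrays, 7 with the comparison's own arrays, and 0 to 51 with each array left out, highest without pBabe 72 h replicate 1. Of the 35 probes called on average in the 10 arrays, 34 were among those called with array weights and 34 among those called without the 3 dim arrays.

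Camera called 1 list at 48 h with all 12 arrays. It called 0 with an estimated correlation, 0 with the series table, 0 with probes good on all 12 arrays, 0 with the date block, 3 with the replicate block, 2 with cyclic loess, 4 without both conflicting arrays and 2 without the 3 dim arrays, and fry called 0. With each array left out it called 0 to 2, with 0 without KLF6 48 h replicate 3, pBabe 48 h replicate 1 or 2 or KLF6 72 h replicate 1, and 2 without pBabe 48 h replicate 3 or pBabe 72 h replicate 1. Of the lists on average, where it called 0, it called 1 with cyclic loess, 3 without both conflicting arrays and 2 without the 3 dim arrays, and 0 to 1 with each array left out (1 without pBabe 72 h replicate 1). At 72 h the range was 0 to 0.

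Of the values of single genes, 1159 kept direction and side of the threshold, 46 passed only under the alternative and 35 changed sign. At 72 h the log2 change of SPINK1 was -0.75 with cyclic loess, -0.24 with the date block, and -2.17 without both conflicting arrays and without the 3 dim arrays. That of MARS1 was -0.040 with the series table, -0.61 with cyclic loess, -0.14 with the date block, and -1.37 without both conflicting arrays and without the 3 dim arrays. BEX1 was at 0.016 with the software's background subtraction, JAM3 at 0.025 with the date block, and ATP5F1C at 0.38 and APOM at 0.24 with the series table; on average ZIC2 was at 0.084 with the background subtraction. With each array left out, the 72 h values ran from -0.36 to 1.39 for TSPO, -1.83 to 0.19 for ERCC6L2, -1.56 to 1.59 for SPINK1, -1.37 to 0.68 for BEX1, -1.26 to 0.23 for APOM, -1.46 to 0.25 for JAM3, -0.65 to 0.74 for MARS1 and -0.058 to 0.68 for ITIH3. The average ran from -1.05 to 0.056 for GSTA1, -1.09 to 0.36 for MT1H and -0.97 to 0.090 for ZIC2.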

Other observations

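Tests chosen after the result was seen were the weight of the library labelled pBabe 72 h replicate 1, the check of that library's label on random probes, and the splits for the average with all 12 arrays and for the difference between times.

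On average in the 10 arrays, 3 of 11 measured acute phase genes were higher with KLF6 and 8 lower; ITIH3 rose and HAMP fell over all probes, and the list did not pass (camera adjusted p = 0.875); 4 members passed adjusted over the list alone, C4BPA, a regulator of complement, at 0.45 ± 0.14 and FGB, a fibrinogen chain, at -0.46 ± 0.14 among them. Of 17 complement and coagulation genes 12 were higher (median 0.16, camera adjusted p = 0.0578), with C8G at 0.78 ± 0.17, MASP2, a protease of the lectin pathway, at 0.49 ± 0.13 and PROC, protein C, at 0.37 ± 0.10 past the threshold adjusted over the list alone. Of 20 secreted and carrier proteins 14 were lower (median -0.07, mean -0.12, camera direction up, adjusted p = 0.932). TTR was at 0.51 ± 0.13 and VTN at 0.54 ± 0.15, among 6 members past the threshold adjusted over the list alone and 0 over all probes.

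The oxidative stress list, with TXNRD1 called, was lower in 14 of 19 members (median -0.08, camera adjusted p = 0.0772); TXN, thioredoxin, was at -0.65 ± 0.20 and NQO1, a quinone reductase, at -0.89 ± 0.31. Of 13 oncofetal and liver cancer genes 7 were higher (median 0.01, mean -0.12, camera direction down, adjusted p = 0.520). SPINK1 passed over all probes, and CD24, a surface marker of liver progenitor cells, at 1.36 ± 0.35 and DLK1, a fetal liver protein, at 0.36 ± 0.12 also passed adjusted over the list alone. Of 16 matrix and TGF-beta responsive genes 10 were higher (median 0.08, camera adjusted p = 0.732). SPARC was at -0.67 ± 0.13, CCN2 at 0.70 ± 0.21 and TIMP2 at 0.40 ± 0.13, all past the threshold adjusted over the list alone and not over all probes. The 23 measured genes of G2 and mitosis, 9 higher and 14 lower, did not pass (median -0.08, camera adjusted p = 0.414), and 0 passed adjusted over the list alone.

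The first pattern is that 0 probes passed with all 12 arrays for the average KLF6 effect and 35 without the 2 conflicting arrays. A KLF6 effect absent at 72 h is argued against. Over 200 probes chosen at 48 h the 72 h effect had a slope of 0.637 (0.579 to 0.693) on the 48 h effect. Random sets gave -0.047 to 0.055, and 183 of 196 probes kept their direction. A smaller effect at 72 h stays open. The interval resamples probes and not the 2 arrays per group at 72 h, and choosing probes at 48 h can itself lower the slope. Weak hybridization of the library labelled pBabe 72 h replicate 1 stays open. Its array weight was 0.0272. Without that array alone 7 probes passed, 3 higher and 4 lower, and 1611 had an unadjusted limma p under 0.05. Without pBabe 72 h replicate 2, 7 passed, 6 higher and 1 lower, with 1188 unadjusted. Without replicate 3, 4 passed, all higher, with 1183 unadjusted. The number that passed does not set that library apart, while the unadjusted number was the highest of these without it. Leaving it out would also take out an exchanged label, so these values cannot decide. An exchanged label stays open for the library labelled KLF6 72 h replicate 1, whose position between the vector (0) and KLF6 (1) arrays was 0.638 (0.437 to 0.838) where the labelled vector arrays reached 0.25 and a KLF6 array stood at 0.602. Over the 35 probes with an average effect that library stood at 0.417, but the arrays used as 0 and 1 had helped to choose those probes. An exchanged label stays open too for the library labelled pBabe 72 h replicate 1, whose position of 2.73 (lower bound 1.82) rests on 29 probes above background and was matched by random probes of the same signs (2.02 to 3.08).

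The second pattern is the 47 probes that rose from 48 h to 72 h in vector cells in the 10 arrays. A defect in 1 place on the slides is argued against: the median distance to the nearest other probe, 19.6 spots, was at percentile 88.3 of random sets. The date in the file names is argued against, since in KLF6 cells the later arrays of a time were not higher than the earlier, the larger of 2 differences being -0.0459 of the rise; the date cannot be tested within vector cells. A change of slide lot between the times cannot be told apart from time, because 100% of the probes were also higher at 72 h in KLF6 cells and the labels give no lot. A response of the cells to time in culture stays open and could not be tested apart from the lot.

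The third pattern is the 35 probes with an average KLF6 effect in the 10 arrays. Within the earlier date at 48 h the median effect was 0.973 of the average effect and 35 of 35 probes kept their direction. Those arrays had also helped to choose the probes, so this check cannot decide on the date. With a date block 26 probes passed in the 10 arrays. With the number of good probes as a covariate for the brightness of the arrays, the median effect was 1.00 times as large. Of the 35 probes 34 still passed, among 351. This check cannot decide on brightness either, since the same arrays had helped to choose the probes. The 2 vectors also differed little in good probes over both times together, so the covariate could hardly move the average effect. At 72 h alone both KLF6 arrays kept (12112 and 13514 good probes) were dimmer than both vector arrays kept (16253 and 15391). Chance is argued against by the splits: the real one gave 35 probes and was the 1 of 60 splits that did, the highest other giving 1. That is the smallest share that 60 splits allow. The splits treat the arrays as separate samples, and the labels do not say that they were separate infections. As a hypothesis found and tested on the same data, an effect of KLF6 on these genes may be what these 35 probes show, although the level of KLF6 was not analysed here.

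The other splits of the arrays gave less. With all 12 arrays the real grouping gave 0 probes for the average and for the difference between times, and 100 of 100 splits gave as many, with a highest other of 1 for each, so chance cannot be excluded there. For 48 h, 72 h and each arm's change with time, 10 of 10 splits gave as many as the real 0; the highest others were 0 at 48 h, 5 at 72 h, 2 with the vector and 0 with KLF6, and these splits are too few for a share under 0.05. The 5 came from the split that put KLF6 72 h replicates 1 and 2 with pBabe 72 h replicate 1. At 48 h in the 10 arrays the real grouping gave 9 probes and the highest other 0, with 1 of 10 splits as large, which is too few for a share under 0.05.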
